A study of Mus musculus with 6 samples.

How the data were processed

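Gene expression was measured on Affymetrix mouse expression arrays in sorted bone marrow progenitors from control mice and from mice lacking c-Myc and N-Myc (double knockout, dKO), with 3 arrays per group. Per the labels' protocols, RNA of the sorted cells was extracted with Trizol, amplified in 2 rounds with a Nugen whole-transcript kit and labelled with biotin, and the labels also name Affymetrix labelling kits. The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes; RMA corrects background, quantile-normalizes and summarizes the probes of each probe set. Its version, and whether all 6 arrays went through it together, are not given in the sources used here. Array medians lay between 5.90 and 5.94, and single values between 1.53 and 13.9. RMA values of dim probe sets shrink towards the background, so fold changes of genes near the lower end are understated. Detection calls and scanner files were not used here, and the small number of arrays limits the precision.

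The table held 45101 probe sets, of which 64 were Affymetrix controls. The platform annotation gave 1 gene symbol to 34945 of the others, several symbols to 932 and no name to 9160. Of those with 1 symbol, 34741 were matched through their gene identifier to a RefSeq table of assembly GRCm38.p6, used only to update symbols and to find neighbouring genes. Each gene was represented by the named probe set with the highest mean over the 6 arrays, which gave 18193 genes; of the 1086 genes called below, 613 had several probe sets and 69 had a probe set of opposite sign. Probe sets are known by their identifiers only, so members of families with similar sequences, such as granzymes, T cell receptor segments, killer receptors, globins and ribosomal proteins with their pseudogenes, are uncertain as single genes.

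Groups were taken from the sample titles. The comparison of dKO with control used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Means are given with the SD over 3 arrays, and log2 fold changes (dKO minus control) with the standard error of the limma fit. Each array is a separate pool of mice, so the errors describe the spread between pools. The 28 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Both were adjusted over the 28 lists, with fry beside them. The version with an estimated correlation also takes its degrees of freedom from the few arrays, so its lost calls do not measure correlation alone. Counts of list members are given over all genes tested, and beside that adjusted over the list alone. The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took Myc and Mycn, the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose groups did not overlap, up to 4 members with the smallest p from each list, the genes of the sort gate and Gzmb. Max, Prf1, Gp9, Gp6, Clec1b and Ifi27l2a were named after their values were seen.

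The steps were tested on simulated data with the arrays' own means and spreads, with 200 changed genes among 18193 in each of 20 runs of the 3 against 3 comparison. The fit recovered 0.977% of genes changed 1.5-fold, 27.3% of those changed 2-fold and 83.7% of those changed 4-fold, and 3.47% of its calls were false. A shifted list was found in 20 of 20 runs and an unshifted list in 0. Genes were simulated independently, so these list results do not cover lists whose members vary together. Changes under 2-fold were mostly missed in this setting. The data gave 1086 calls, against 200 genes simulated as changed. More changed genes make the adjusted threshold easier to pass, so the recovery in the data may be higher. Alternatives covered the filter on dim probe sets, the choice of probe set, 3 other scalings, the variance model, array weights, a replicate block, a plain t-test, other thresholds and leaving out each array. Settings without the pools that showed Xist signal, and with that signal as a covariate, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.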

Results

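The data are 6 array profiles of bone marrow cells sorted as negative for lineage markers and positive for Sca1, CD150 and CD48, cells that the study describes as committed progenitors. Kit is not named in the gate. In the dKO mice the MxCre transgene, which interferon switches on, deletes the floxed alleles of both c-Myc and N-Myc, transcription factors that drive growth and division. The controls carried the same alleles without MxCre. All mice were 8 weeks old and on a mixed background, and both groups received 2 daily injections of the interferon inducer pI-pC, the last 3 days before the cells were taken. Each of the 3 control arrays holds a pool of 2 mice and each of the 3 dKO arrays a pool of 3. The tissue label of control 1 names long-term stem cells, whereas its gate and title match the other arrays. The comparison asks which transcripts of these progenitors differ when both genes are lost. Only the dKO mice carried MxCre, so an effect of the transgene itself cannot be told apart from that loss.

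Myc and 1 of the 3 Mycn probe sets were lower in all 3 dKO pools than in any control pool. Myc, measured by 1 probe set, stood at 10.74 ± 0.24 in control and 7.77 ± 0.29 in dKO (log2, mean ± SD, n = 3), so it fell by 2.97 ± 0.21 (SE), or 7.84-fold (limma, adjusted p = 0.00014). The Mycn probe set that separated the groups best stood at 9.33 ± 0.35 in control and 4.05 ± 0.68 in dKO and fell by 5.27 ± 0.34 (SE), or 38.6-fold (adjusted p over all probe sets = 0.00029). The other Mycn probe sets differed from this. The brightest on average, which represents the gene in the comparison of all genes, changed by -0.83 ± 0.27 (SE) with adjusted p = 0.133, and by -1.14 with adjusted p = 0.0161 without dKO 3, and its arrays overlapped between the groups. The dimmest changed by 0.34 and did not pass, though it was higher in all 3 dKO arrays. Whether any of these probe sets lies within the deleted exons is not given in the labels, so a probe set outside them checks nothing about the deletion. In the MYC network list 4 of 14 members were lower and 0 higher (6 and 0 adjusted over the list alone). The median log2 fold change was -0.36, with camera adjusted p = 0.000472, or 0.113 with an estimated correlation. The list holds the targeted genes Myc and Mycn themselves, so its fall is partly given by the design, and it was not tested without them. Besides Myc the lower members were Mxi1 (-1.26), Mlxip (-0.85) and Mycl (-1.24), of which Mycl lay near the threshold (adjusted p = 0.047). These 3 calls rested on single arrays, with adjusted p up to 0.0595 for Mxi1 without control 3, and 0.112 for Mlxip and 0.169 for Mycl without control 2. The number of lower genes was 1 without control 3 and 2 without control 1, control 2 or dKO 1, and the median was -0.22 without dKO 2. Max, the partner of MYC proteins, changed by -0.09 ± 0.21 and did not pass.

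**Figure D1:**
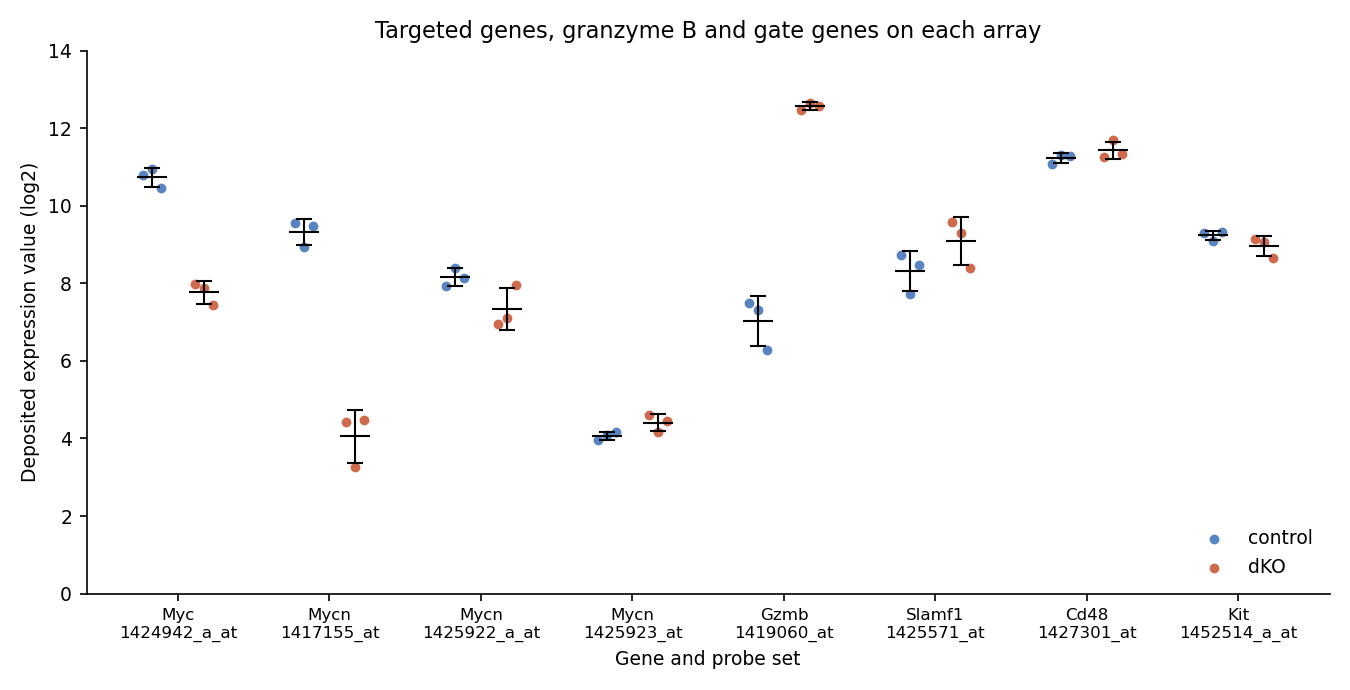
Deposited log2 expression of Myc, the 3 Mycn probe sets, Gzmb and the gate genes Slamf1, Cd48 and Kit on each array (points: 3 control and 3 dKO arrays; lines: mean ± SD). Myc, the leftmost Mycn probe set and Gzmb separate the groups fully, whereas the Cd48 means of 11.23 and 11.43 lie within the spread between arrays.

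With each gene taken by its brightest probe set, granzyme B had the highest log2 fold change and the lymphoid enzyme gene Dntt the lowest, although the Mycn probe set that separated the groups best fell further (-5.27). In all, 1086 of 18193 genes changed, 567 higher and 519 lower in dKO, a balance that turned to 400 and 427 without dKO 2. Of these, 419 were higher and 345 lower by at least 2-fold, and 98 and 68 by at least 4-fold. The groups did not overlap for 4262 genes, or 23.4%, against 10% by chance. The number of changed genes was 572 without control 2, 576 without control 3 and 683 without dKO 1, and 578 without control 1 and dKO 1 together, the pools with Xist signal.

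Among the 10 genes with the highest fold changes, Gzmb, a protease of cytotoxic granules, rose from 7.03 ± 0.66 to 12.57 ± 0.10 (n = 3), a log2 fold change of 5.54 ± 0.30 or 46.4-fold (limma, adjusted p = 2.9e-05). Gzmc of the same family rose by 3.85 ± 0.17. Trgv4, a variable segment of the T cell receptor gamma chain, rose by 5.39 ± 0.25, although its 3 probe sets ranged from 0.41 to 5.47. Slc6a4, the serotonin transporter, rose by 4.88 ± 0.22, Ppbp, a platelet chemokine precursor, by 4.87 ± 0.40, and Thbs1, a thrombospondin stored in platelets, by 4.09 ± 0.18. Cxcl3, a neutrophil attractant, rose by 4.18 ± 0.58, Il1b, an inflammatory cytokine, by 3.94 ± 0.24, and Timp3, an inhibitor of matrix proteases, by 3.95 ± 0.30. Cdkn1a, the cell cycle inhibitor p21, rose from 6.51 ± 0.79 to 10.52 ± 0.36, by 4.01 ± 0.36 or 16.1-fold (adjusted p = 0.000457). By the rule that picked these genes, all 3 dKO arrays lay above all 3 control arrays in each. Their calls held with each array left out in turn.

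Among the 10 genes with the lowest fold changes, Dntt, the terminal transferase of early lymphoid cells, fell from 10.89 ± 0.37 to 5.90 ± 0.55 (n = 3), a log2 fold change of -4.99 ± 0.29 or 31.8-fold (limma, adjusted p = 4.73e-05). Klf4, a transcription factor of monocytes among other cells, changed by -4.69 ± 0.26, and Chil3, a secreted chitinase-like protein of myeloid cells, by -4.35 ± 0.31. Ptpro, a receptor phosphatase, changed by -4.18 ± 0.53, and Met, the receptor for hepatocyte growth factor, by -3.83 ± 0.36. F13a1, a subunit of coagulation factor XIII, changed by -3.80 ± 0.32, Cnn3, an actin-binding calponin, by -3.44 ± 0.26, and Ly86, a surface protein of B cells and myeloid cells, by -3.10 ± 0.21. The remaining genes were 4930447C04Rik (-3.16 ± 0.57) and Ifi207 (-3.12 ± 0.69), whose dKO arrays varied most, with SDs of 1.43 and 1.60. Ifi207 lost its call without control 1 (adjusted p = 0.0761), control 2 (0.115), dKO 1 (0.0932) or dKO 3 (0.103).

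**Figure D2:**
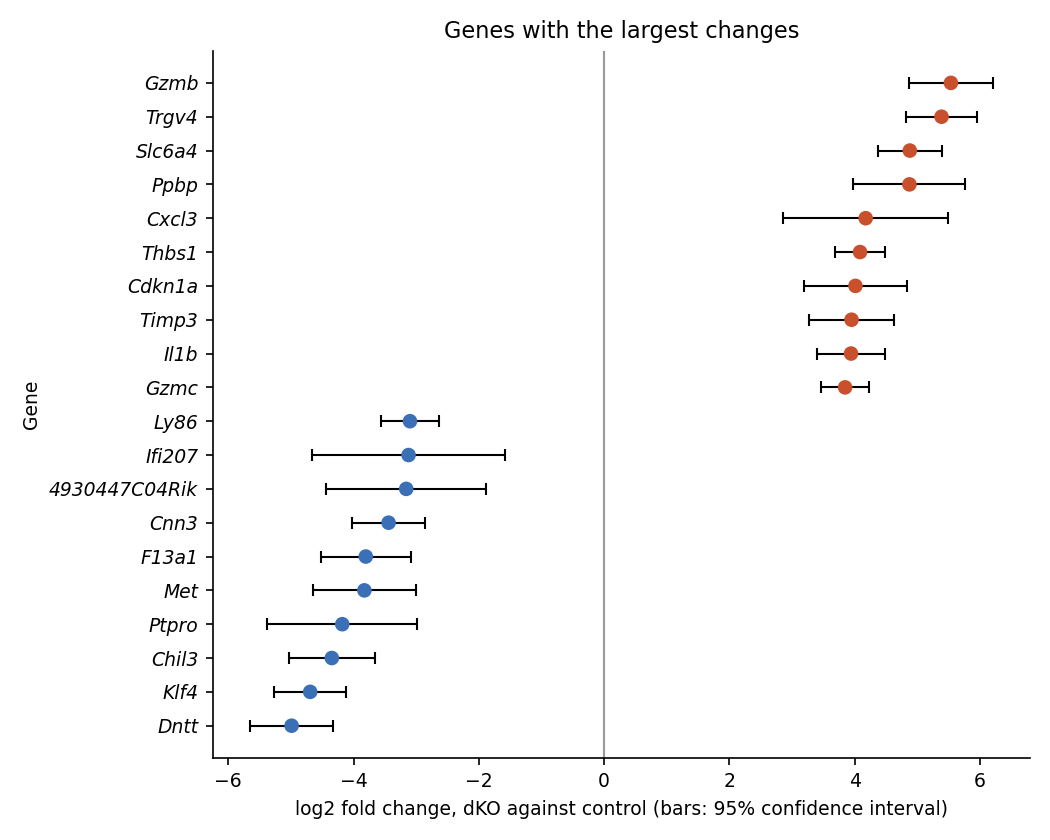
Log2 fold change of dKO against control for the 10 genes with the highest and the 10 with the lowest values among those past the threshold (points: limma estimates from 3 arrays per group; bars: 95% confidence interval). The estimates run from 5.54 for Gzmb to -4.99 for Dntt, and no interval reaches 0, which passing the threshold requires.

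Genes of ribosome production were lower in dKO as lists. Of 39 ribosome biogenesis genes 9 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 fold change of -0.46 (camera adjusted p = 8.41e-11; adjusted p = 0.0488 with an estimated correlation, lost without each single array at 0.0905 to 0.132). The nucleolar GTPase gene Gnl3 fell by 1.52 ± 0.17 (adjusted p = 0.00137), and Dkc1, which encodes the pseudouridine synthase dyskerin, changed by -0.95 ± 0.17, losing its call without control 2 (adjusted p = 0.058). The number of lower genes was 3 without control 2 and 5 without control 3. Of 49 ribosomal protein genes 17 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.60 and camera adjusted p = 1.63e-18, or adjusted p = 0.118 with an estimated correlation. Examples were Rpl12 (-2.10 ± 0.21), Rpl14 (-2.06 ± 0.23), Rps26 (-1.24 ± 0.19) and Rplp0 (-1.15 ± 0.17). The number of lower ribosomal protein genes was 9, 7 and 6 without control 1, 2 and 3, and 8 and 11 without dKO 1 and 2. Without both pools with Xist signal it was 4, and 2 ribosome biogenesis genes were lower.

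Other growth genes moved less evenly. Of 22 further textbook MYC targets 7 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.38e-07; adjusted p = 0.0488 with an estimated correlation, lost without each single array at 0.0905 to 0.132). Tfrc, the transferrin receptor, fell by 1.35 ± 0.17, whereas Ccnd2, cyclin D2, rose by 1.12 ± 0.21 and lost that call without dKO 2 (adjusted p = 0.0513). The number of lower genes was 4 without control 1 or dKO 2 and 1 without control 2, control 3 or dKO 1, 4 with the replicate block and 2 without both pools with Xist signal. Of 20 nucleotide synthesis genes 3 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.40 and camera adjusted p = 5.93e-05, or adjusted p = 0.113 with an estimated correlation. The purine synthesis gene Atic fell by 1.28 ± 0.20, and 1 gene was lower without control 1, control 2 or control 3 and 0 without both pools with Xist signal. Of 28 translation factors and tRNA synthetases 2 fell and 1 rose (the same numbers adjusted over the list alone), and the list's median of -0.05 did not pass (camera adjusted p = 0.0666). The list passed downwards without control 1 (camera adjusted p = 0.0455), without dKO 2 (0.0265) and with the mean of each gene's probe sets (0.035), with medians of -0.14, -0.15 and -0.14. The elongation factor gene Eef1b2 fell by 0.95 ± 0.17; the other calls, Eef2 (-0.86) and Aars (0.86), were lost without control 3 (adjusted p = 0.0772 and 0.0818) and without dKO 1 (0.0582 and 0.0565), Eef2 also without control 2 (0.0618) and Aars without control 1 (0.0652). Of 16 glycolysis and lactate genes 3 fell and 0 rose (4 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.304), with a median of 0.07, a mean of -0.21 and a downward test direction. Without single arrays the median ran from -0.02 (dKO 3) to 0.11 (control 2). The fallen genes were Pdk1, a kinase that restrains pyruvate oxidation (-1.75 ± 0.22), the hexokinase Hk2 (-1.58 ± 0.23) and the lactate transporter Slc16a1 (-1.74 ± 0.33), the last losing its call without control 3 (adjusted p = 0.0571) or dKO 2 (0.055).

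In the cell cycle lists few genes besides p21 passed the threshold. Of 32 S phase genes 0 passed the limma test in either direction, also adjusted over the list alone. The median was -0.03 (camera adjusted p = 0.144), with -0.08 without control 3 or dKO 2, and by fry the list passed downwards (adjusted p = 0.0407). Over all genes 3318 lay under an unadjusted p of 0.05. Ung (-0.60 ± 0.16) and Cdt1 (-0.61 ± 0.18) had the smallest p of the list. Of 29 G2 and M phase genes 2 fell and 0 rose (the same adjusted over the list alone), with a median of -0.20. The camera adjusted p was 0.000502, or 0.287 with an estimated correlation, and by fry the list did not pass (adjusted p = 0.0637). The fallen genes were Kif23 (-0.85) and Racgap1 (-0.80), partners in cytokinesis. The number lower was 1 without control 3 and 0 without control 1, control 2, dKO 1 or dKO 2, with adjusted p up to 0.09 for Kif23 and 0.113 for Racgap1, both without control 2. Of 18 CDK inhibitor and quiescence genes 2 rose, Cdkn1a and Gadd45b, and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.33 and camera adjusted p = 0.0149, or adjusted p = 0.27 with an estimated correlation. That list lost its call without dKO 1 (median 0.19, camera adjusted p = 0.0783) and without both pools with Xist signal (0.0556). The median was 0.51 under the filter on dim genes and 0.21 without _x_at and _s_at probe sets. Gadd45b rose by 0.74 ± 0.17 and lost its call with each array left out, with adjusted p from 0.0566 without dKO 3 to 0.139 without control 2.

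Targets of p53 were higher as a list. Of 18 measured, 3 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.86 and camera adjusted p = 2.15e-06, or adjusted p = 0.23 with an estimated correlation. Besides Cdkn1a these were the stress-response genes Sesn2 (1.37 ± 0.22) and Plk2 (2.10 ± 0.35; its other probe set changed by 0.17), and without dKO 3 the number was 8. The median was 0.53 without dKO 1. Of 14 BCL2 family genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), and the list with its median of 0.19 did not pass (camera adjusted p = 0.177). By fry the list passed upwards (adjusted p = 0.0174). The median was 0.28 without dKO 2 and 0.06 without dKO 3. Both risen members restrain apoptosis. Bcl2l1 rose by 1.63 ± 0.31 and lost its call without dKO 1 (adjusted p = 0.0553) or dKO 2 (0.0598). Bcl2 rose by 0.78 ± 0.16 and kept it only without dKO 3, with adjusted p up to 0.1 without control 3.

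Genes of cytotoxic granules and markers of T and NK cells were higher as lists. Of 18 cytotoxic granule genes 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 4.21e-08; adjusted p = 0.0488 with an estimated correlation, lost without each single array at 0.0905 to 0.132). Under the filter on dim genes the median was 1.58. The list was chosen knowing that the study's paper discusses granzyme B, so it is not independent evidence of its direction. Next to Gzmb and Gzmc, the granule membrane gene Nkg7 rose by 1.94 ± 0.18 and the protease gene Ctsw by 1.60 ± 0.29, which lost its call without control 2 (adjusted p = 0.0594) or dKO 2 (0.0534). The number of risen genes was 3 without control 2, 4 without control 3 and 3 without dKO 2. The other granzymes apart from Gzma lay between -0.02 and 0.47 and did not pass. The perforin gene Prf1 differed between its probe sets: the brighter changed by 0.17 ± 0.16 and did not pass, and the dimmer by 2.97. Of 17 T and NK cell markers 8 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.03 and camera adjusted p = 2.15e-06, or adjusted p = 0.113 with an estimated correlation. The interleukin 2 receptor gene Il2rb rose by 1.80 ± 0.28, the NK receptor gene Klrk1 by 1.76 ± 0.27, the transcription factor gene Gata3 by 1.25 ± 0.21 and the adhesion receptor gene Cd2 by 1.28 ± 0.21. Without control 3 the number of risen markers was 5.

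Lymphoid, dendritic and monocytic genes were lower as lists. Of 18 B cell and lymphoid progenitor genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.70 and camera adjusted p = 4.8e-06, or adjusted p = 0.19 with an estimated correlation. The median was -1.06 without control 1 and -0.41 without dKO 1, and -0.33 with the mean of probe sets and -0.44 without _x_at and _s_at probe sets, and 3 genes were lower under the filter on dim genes. After Dntt these included the cytokine receptor Flt3, which marks early lymphoid potential (-2.73 ± 0.27), the recombinase Rag1 (-2.28 ± 0.29) and the transcription factor Spib (-1.94 ± 0.26). Of 15 plasmacytoid and dendritic cell markers 2 fell, Cd209a (-1.79 ± 0.26) and Bst2 (-1.16 ± 0.18), and 0 rose, with a median of -0.55 and camera adjusted p = 0.000126, or adjusted p = 0.19 with an estimated correlation. Adjusted over the list alone 7 were lower and 1 higher, and 4 were lower over all genes without dKO 3, with the mean of probe sets or with the Xist covariate. Of 21 granulocyte and monocyte genes 3 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.58. The camera adjusted p was 2.98e-06, or 0.215 with an estimated correlation, and by fry the list did not pass (adjusted p = 0.0718). The fallen genes were Irf8, a regulator of monocyte and dendritic cell fate (-2.33 ± 0.30), Csf1r, the receptor for macrophage colony-stimulating factor (-2.44 ± 0.35), and Lyz2 (-1.62 ± 0.24), and without control 1 the number was 6. It was 8 with the replicate block or the Xist covariate, 7 without both pools with Xist signal and 5 with the mean of probe sets, and under the filter on dim genes the median was -1.27. Ms4a3, a granulocyte progenitor gene, rose by 1.29 ± 0.27 and lost that call without control 1 (adjusted p = 0.0784), control 3 (0.0857), dKO 2 (0.0649) or dKO 3 (0.0657).

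Megakaryocyte, mast cell and erythroid genes were higher as lists. Of 18 megakaryocyte genes 10 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.99 (camera adjusted p = 1.95e-09; adjusted p = 0.0488 with an estimated correlation, lost without each single array at 0.0905 to 0.178). With Ppbp, the platelet adhesion gene Selp rose by 3.52 ± 0.17, the integrin gene Itgb3 by 2.00 ± 0.20 and Pf4, platelet factor 4, by 1.53 ± 0.17. The platelet receptor genes Gp9 (0.25), Gp6 (0.07) and Clec1b (-0.29) did not pass, and the number of risen genes was 6 without control 2. Of 13 mast cell and basophil genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.58 and camera adjusted p = 1.02e-06, or adjusted p = 0.118 with an estimated correlation. Under the filter on dim genes the median was 1.87. These included the lipoxygenase Alox5 (2.71 ± 0.18), the proteases Cma1 (2.53 ± 0.32) and Mcpt8 (2.42 ± 0.33), and the IgE receptor chain Fcer1a (2.24 ± 0.36). Of 17 erythroid genes 5 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.77 and camera adjusted p = 1.28e-06, or adjusted p = 0.118 with an estimated correlation. Aqp1, Gypc and Rhag, genes of the red cell membrane, rose by 0.93 ± 0.17, 1.13 ± 0.21 and 1.57 ± 0.35, and Icam4 fell by 0.98 ± 0.21. The numbers higher were 3 without control 1, 2 without control 3 and 0 without control 2 or dKO 1, and 3 after quantile normalization again or cyclic loess. Adjusted p reached 0.0574 for Aqp1 without control 3, 0.0671 for Gypc and 0.114 for Rhag without control 2, and 0.0921 for Icam4 without control 1, whose call was kept only without dKO 3.

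The stem cell list moved both ways. Of 26 genes of haematopoietic stem cells 6 rose and 2 fell (7 and 4 adjusted over the list alone), and the list did not pass, with a median of -0.19, a mean of 0.07 and an upward test direction (camera adjusted p = 0.884). That direction was downward without control 2 or dKO 2, and the median was -0.11 without control 3 and 0.0047 without dKO 1. The immediate early factor Egr1 rose by 3.68 ± 0.29, and the blood transcription factors Gata2 and Tal1 by 1.34 ± 0.24 and 1.13 ± 0.18. Tek, the angiopoietin receptor, fell by 2.86 ± 0.27. Of these genes 3 were higher without control 2, and 1 was lower without control 1, control 2, control 3 or dKO 1. Without both pools with Xist signal 2 were higher and 1 lower. The gate genes did not pass: Slamf1, which encodes CD150, changed by 0.78 ± 0.34 (adjusted p = 0.264), Cd48 by 0.20 ± 0.18 and Kit by -0.29 ± 0.19, and the gate list had a median of 0.20 over 3 measured genes, with 0 passing adjusted over the list alone (camera adjusted p = 0.702; its upward test direction was downward without dKO 2). The gate median was 0.13 without control 1 and 0.07 without dKO 2. Slamf1 stood at 9.58 and 9.31 in dKO 1 and dKO 2 and at 8.40 in dKO 3, against 7.74 to 8.74 in control. Ly6a, the gene of Sca1, is not named among the probe sets used here.

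Markers of macrophages and stroma did not pass as lists with all arrays and genes, but did in some other settings. Of 14 macrophage markers 1 rose and 2 fell (1 and 3 adjusted over the list alone), with a median of 0.30 and a downward test direction (camera adjusted p = 0.976). The median was 0.63 without control 1, 0.03 without control 3 and 0.09 without dKO 3. Its test direction was upwards without control 1 or dKO 1, and without both, the pools with Xist signal, the list passed upwards with a median of 0.62 (camera adjusted p = 0.0478). Spic, a factor of iron-recycling macrophages, rose by 1.47 ± 0.21, and the scavenger receptor Cd163 fell by 1.94 ± 0.30. Cd68 fell by 0.90 ± 0.18 and lost its call without any of control 1 (adjusted p = 0.0557), control 2 (0.0769) or control 3 (0.0701), and 2 markers were higher without control 1. Of 13 stroma and endothelium markers 2 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.087). It passed upwards without dKO 2 (camera adjusted p = 0.0392) and among the 5 members left by the filter on dim genes (0.00074). Col1a2, a collagen chain, rose by 2.70 ± 0.45, although its 3 probe sets ranged from -0.21 to 2.70. Sparc, a matrix protein, rose by 2.01 ± 0.38 (probe sets from 0.09 to 2.01) and lost its call without dKO 1 (adjusted p = 0.0509) or dKO 3 (0.052), and the fall of Cdh5 (-0.97 ± 0.23) was kept only without control 1, with adjusted p up to 0.14 without control 2. Of 25 adhesion and homing genes 5 rose and 2 fell (9 and 5 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.177), and of 0.14 without control 2 and 0.06 without dKO 3. Next to Itgb3, the junction gene Jam2 rose by 1.48 ± 0.22, although its 5 probe sets ranged from 0.14 to 1.48 and their mean (0.49) did not pass (adjusted p = 0.147), and the collagen-binding integrin Itga1 fell by 1.61 ± 0.28. The numbers higher were 2 without control 1 or control 3 and 3 without dKO 2, and 1 gene was lower without control 2, control 3, dKO 1 or dKO 3.

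The interferon response list was higher in dKO with the preset correlation, although both groups had received pI-pC. Of 29 measured, 10 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 0.63 and camera adjusted p = 4.1e-08, or adjusted p = 0.0576 with an estimated correlation. The chemokine gene Cxcl10 rose by 3.71 ± 0.31, Usp18, a brake on interferon signalling, by 1.97 ± 0.22, the nucleic acid sensor Zbp1 by 1.94 ± 0.18 and Ifit1 by 1.55 ± 0.22. Bst2 (-1.16) and Ifi27l2a (-1.14) fell, and 1 gene was lower without control 2, control 3, dKO 1 or dKO 2. Without both pools with Xist signal 5 were higher. Of 20 immediate early and heat shock genes 5 rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.50. The camera adjusted p was 0.00912, or 0.361 with an estimated correlation, and by fry the list did not pass (adjusted p = 0.118). Egr1, Socs3 (2.42 ± 0.29), a brake on cytokine signalling, and Ier3 (1.35 ± 0.19) rose, and Klf4 was the fallen gene, with 2 lower without control 2. The median was 0.31 without dKO 3, 3 genes were higher under the filter on dim genes, and without both pools with Xist signal the median was 0.27 and the list did not pass (camera adjusted p = 0.0944).

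**Figure D3:**
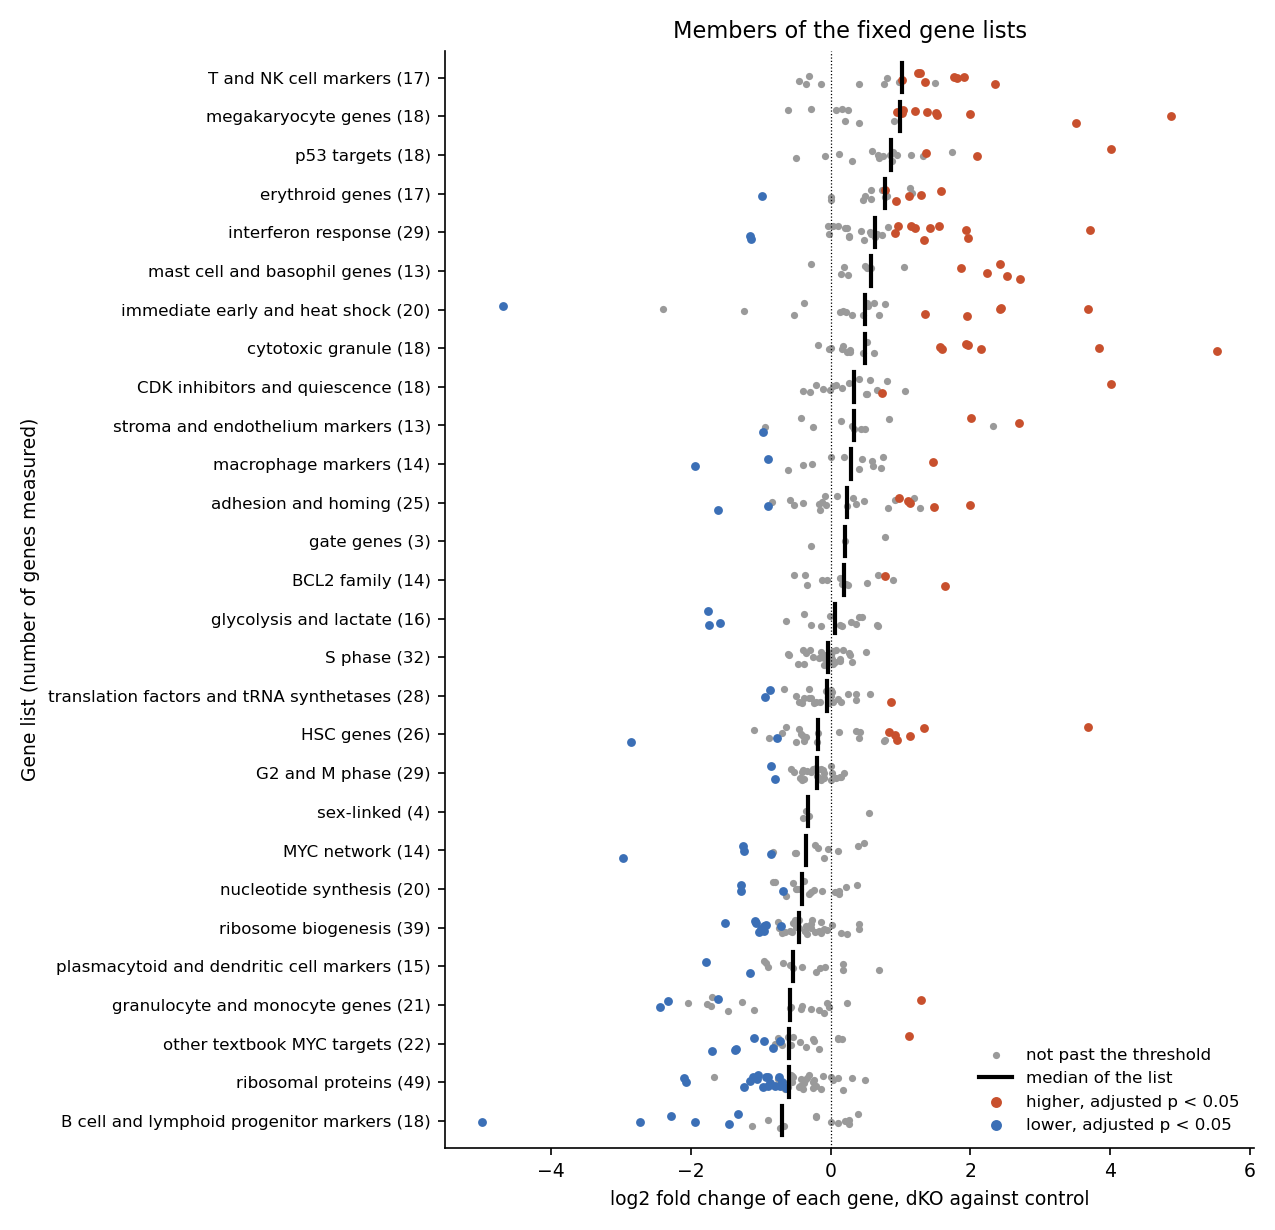
Log2 fold change of dKO against control for each measured member of the 28 gene lists, ordered by the list's median (points: genes, red where higher and blue where lower past the threshold, grey otherwise; black bars: medians; numbers of genes in brackets). The medians run from -0.70 for B cell and lymphoid progenitor markers to 1.03 for T and NK cell markers, and in the ribosomal protein list 17 genes are lower and 0 higher.

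Of the 28 lists 18 passed with the preset correlation, 9 upwards and 9 downwards, and 4 passed with an estimated one, each at adjusted p = 0.0488. With an estimated correlation 0 lists passed without any single array, under the filter on dim genes, without _x_at and _s_at probe sets, after median centring, with the replicate block or in the settings that treat Xist signal. By that test 5 passed with the mean of probe sets, and 3 after quantile normalization again or cyclic loess. The estimated correlations of the other textbook MYC targets (-0.024) and cytotoxic granules (0.0058) lay below the preset 0.01. Their unadjusted camera p still rose from 2.95e-08 and 7.52e-09 to 0.00365 and 0.00397. Lost calls therefore also reflect the few arrays behind that test, fewer still with 1 left out. By fry, the BCL2 family (upwards, adjusted p = 0.0174) and S phase (downwards, 0.0407) lists passed although they did not by camera. The G2 and M phase (0.0637), granulocyte and monocyte (0.0718) and immediate early and heat shock (0.118) lists did not pass by fry. The other lists past camera with the preset correlation also passed by fry. The arrays separated by group. Over all probe sets except the Affymetrix controls, correlations were 0.981 to 0.986 within control, 0.969 to 0.980 within dKO and 0.956 to 0.971 between groups. Over the same probe sets the first principal component, with 44.0% of the variance, parted the groups. The next, with 21.9%, set dKO 3 apart. The 4 sex-linked genes did not pass as a list (median -0.33, 0 higher and 0 lower, also adjusted over the list alone; camera adjusted p = 0.177), although the list passed downwards without dKO 2 (0.0399) with a median of -0.53, against -0.17 without dKO 3. Xist, the RNA of the inactive X, stood at 9.10 in control 1 and 10.50 in dKO 1 against 5.03 to 5.86 in the other pools. The Y-linked gene Eif2s3y lay between 9.19 and 10.07 in all 6, so control 1 and dKO 1 probably held cells of both sexes. The Y-linked genes were not clearly lower in control 1, however. Kdm5d stood there at 9.39, against 8.95 and 9.20 in control 2 and control 3, and Uty at 7.79, against 7.59 and 7.95. The share of female cells in that pool is therefore unclear. The difference between the 3' and 5' probe sets of Gapdh, a sign of RNA length, was 2.23 ± 0.11 in control and 2.51 ± 0.20 in dKO (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). For actin it was 0.20 in both groups (exact permutation p = 1). The spiked poly-A controls of control 2 read 4.70-fold lower than the mean of the other 5 arrays.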

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

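The tests of admixed T and NK cells, of the sort gate and of granzyme B against other NK transcripts were chosen after the result was seen, as were the settings that treat Xist signal. Outside the comparison of genes, 10092 probe sets without exactly 1 gene symbol were tested in the same way: 122 were higher and 133 lower in dKO (limma), a signal in data that the report does not use. The real grouping gave 1086 changed genes and the highest other of the 10 splits of the 6 arrays gave 0, so 1 split of 10 was as large, and 10 splits are too few for a share under 0.05.

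T and NK cell markers were higher in dKO as a list with the preset correlation (8 of 17 risen). With an estimated correlation that list did not pass (camera adjusted p = 0.113). Among the granzymes Gzma, Gzmb and Gzmc were higher. These rises may come from more mature lymphocytes among the sorted cells. A set of 15 NK transcripts had a median of 1.80 (95% bootstrap interval 1.09 to 1.96) with 11 higher and 0 lower. That bootstrap resampled the transcripts and not the pools, so its interval does not describe the spread between pools. Of the 15, 6 are in the T and NK list and 3 in the cytotoxic list, so the set partly restates those lists. Its brightest genes Gzma, Nkg7 and Ccl5 stood at 11.53, 11.19 and 10.80 in dKO. Klra7 (1.09), Tbx21 (0.81), Klrd1 (0.77) and Prf1 (0.17) did not pass. A set of 16 T cell transcripts, 7 of them in the T and NK list, had a median of 1.0 (0.69 to 1.33 by the same bootstrap) with 8 higher. That median was at the bound of 1 set for it, while Cd6 (-0.01) and Cd28 (-0.31) did not follow. For granzyme B a larger share of the same NK cells cannot be told apart from a change of state of such cells or expression in the progenitors. Its rise lay 3.73 above the median of the NK transcripts. However, 8 of these 15 were dimmer in control by over 0.5, where folds are understated. A further 5 were brighter, where a high baseline would hide a small share. The 2 near its level, Klrk1 and Il2rb, rose by 1.76 and 1.80 against 5.54 for Gzmb, but the test required at least 5 such transcripts. A lineage-negative gate would remove mature lymphocytes, but the antibodies of that gate are not given in the labels, so loss of both genes acting on the progenitors and a changed cell mixture remain side by side.

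With the preset correlation ribosomal protein genes were lower in dKO as a list (17 of 49 fallen), with a median of -0.60. With an estimated correlation the list did not pass (camera adjusted p = 0.118). That median lay below the range of expression-matched lists, whose lower 2.5th percentile was -0.0124, so genes of like brightness did not fall alike. The comparison was meant to test compression of abundant probe sets. Compression shrinks fold changes and would not by itself make a fall, so the comparison does not decide about it. The matched lists draw genes independently, whereas this list's estimated correlation was 0.295, so their range may be too narrow. Further scaling of the deposited values kept the fall but could change its size. After quantile normalization again the median was -0.46 with 12 genes lower. It was -0.60 after median centring and -0.56 after cyclic loess, each with 17 lower. Less the median of all genes, the highest value under these 3 scalings was -0.50. RMA had already normalized these values, so the scalings cannot test that normalization, and its effect stays open. A changed mixture of cells that differ in ribosome content was not tested and stays open. The loss of MYC activity named by the design may lower these genes directly, which remains a hypothesis.

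With the preset correlation B cell and lymphoid progenitor genes were lower in dKO as a list (6 of 18 fallen) and megakaryocyte genes higher (10 of 18 risen). With an estimated correlation the lymphoid list did not pass (camera adjusted p = 0.19). The megakaryocyte list passed (0.0488) but lost that call with any single array left out. Mixed-sex pools as the whole cause are argued against, since without both control 1 and dKO 1 the medians were -0.65 and 0.87, and the smaller share kept was 0.88. The lymphoid median was -1.06 without control 1 alone and -0.41 without dKO 1 alone. It was also -0.51 without control 2 or control 3, pools without Xist signal, and -0.33 with the mean of probe sets. Its size therefore depends on single pools, with or without Xist signal, and on the choice of probe set. A drift of the sort gate in CD150 cannot be told apart from an effect on the cells, because Slamf1 changed by 0.78 ± 0.34, neither past the threshold nor close to 0. Cd48 changed by 0.20 ± 0.18. A changed makeup of the gated progenitors and a change within each cell after the loss of both genes remain open, and bulk RNA of pools does not separate them.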

How the results depend on the processing

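The settings that treat Xist signal were chosen after the result was seen; the others were fixed before the data were examined. None of the named genes past the threshold turned its direction in a setting run, and Myc stayed lower past the threshold in each. Lists past the threshold kept theirs too, and turns lay among results that did not pass. The stem cell median of -0.19 was 0.12 under the filter on dim genes and ran from -0.22 to 0.0047 without single arrays, and its upward test direction was downward without _x_at and _s_at probe sets, with the replicate block, with the Xist covariate and without control 2 or dKO 2. The S phase median was 0.0042 with the mean of probe sets and 0.0071 after cyclic loess, and that of glycolysis was -0.00921 without _x_at and _s_at probe sets and ran from -0.0228 (dKO 3) to 0.11 without single arrays. The macrophage test turned upwards with the mean of probe sets, quantile normalization again, the replicate block, the Xist covariate, without control 1 or dKO 1, and without both, where it passed; the gate gene test turned downwards without dKO 2. Xist, at 0.55, ran from -1.09 (dKO 1) to 1.79 (control 1) without single arrays. The excess of higher over lower genes also turned, to 581 and 610 under the filter on dim genes, 794 and 819 at an adjusted p threshold of 0.1, 848 and 849 with array weights and 400 and 427 without dKO 2. Of the 1086 changed genes between 895 and 1076 were called again in the same direction under the other scalings, variance models, array weights, the mean of probe sets, the probe sets without _x_at and _s_at and the replicate block, and 918 of the 918 that stayed in the filter on dim genes. The plain t-test, which does not share variance between genes, called 70 genes, 46 higher and 24 lower, of which 64 were among the 1086. Array weights called 1697, with 849 lower. An adjusted p threshold of 0.1 gave 819 lower genes, a further 2-fold threshold left 345 lower, and testing every probe set gave 800 lower probe sets. Without single arrays the number of changed genes ran from 572 (control 2) to 1081 (dKO 3), of higher genes from 331 (control 3) to 617 (dKO 3) and of lower genes from 236 (control 2) to 464 (dKO 3). Without both pools with Xist signal it was 578, 303 higher and 275 lower. Fewer arrays give these fits less power; for the others the cause was not tested. With an estimated correlation 4 lists passed in place of 18, 5 with the mean of probe sets, 3 after quantile normalization again or cyclic loess (the interferon response among them) and 0 in the other settings in which lists were tested, leaving out single arrays included. These lost calls also reflect the few arrays behind that test.

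The brightest Mycn probe set, which did not pass, was past the threshold as the mean of the gene's probe sets (-1.92) and with array weights (-1.05), and without single arrays it ran from -0.63 (dKO 1) to -1.14 (dKO 3). Medians of lists past the threshold moved most under the filter on dim genes, to 1.58 for cytotoxic granules, 1.87 for mast cells and -1.27 for granulocytes and monocytes, against 0.50, 0.58 and -0.58. The lymphoid median of -0.70 was -0.33 with the mean of probe sets and -0.44 without _x_at and _s_at probe sets, and that of CDK inhibitors 0.51 under the filter and 0.21 without those probe sets, against 0.33. Without both pools with Xist signal 4 ribosomal protein and 2 ribosome biogenesis genes were lower, in place of 17 and 9, and 5 interferon genes higher in place of 10. Of the named genes 8 lost their call with the mean of probe sets (Mycl, Gart, Eef2, Racgap1, Gadd45b, Bcl2, Cdh5 and Jam2) and 7 gained one; 25 lost it without both pools with Xist signal and 81 by the plain t-test. Of the 10 lists that did not pass, 3 passed without dKO 2 (translation factors, stroma and sex-linked). The replicate numbers gave no clear sign of pairing. Deviations of same-numbered arrays correlated at 0.06, -0.00045 and 0.02, against -0.05 to 0.04 for the other pairs. Control 1 and dKO 1, the pools with Xist signal, share a number, so pairing is not excluded. With the replicate block 999 genes were called. Signal over background was not given, so dim genes are limited to understated folds.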

Other observations

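The test of small nucleolar RNA host genes was chosen after the result was seen, and the genes of the next paragraph were chosen after their values were seen.

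Several single genes outside the fixed lists had large changes; they were picked by eye, form no list and were not tested for enrichment. Cish, a cytokine-induced signalling inhibitor, rose by 3.77 ± 0.21 (limma, adjusted p = 2.9e-05), Pim2 by 2.61 ± 0.24, Socs2 by 2.41 ± 0.26, Osm by 2.24 ± 0.20 and Id2 by 2.17 ± 0.25, whereas the repressor gene Bcl6 fell by 1.48 ± 0.35 and kept its call in 1 of the 6 fits that left out an array. Il2ra, a chain of the interleukin 2 receptor, rose by 2.61 ± 0.32, Cd69 by 2.33 ± 0.22, Tnfrsf9 by 2.30 ± 0.28, Tnfrsf18 by 2.00 ± 0.17 and Ifng, the gene of interferon gamma, by 2.26 ± 0.43, which kept its call in 3 of those 6 fits. Il6 (3.71 ± 0.55), Ptgs2 (3.23 ± 0.37) and Cxcl2 (3.15 ± 0.30) were higher from control levels of 3.77, 2.25 and 2.81, near the lower end of the arrays. The globin gene Hbb-b2 rose by 3.82 ± 0.18, although its probes may also bind other beta globins, and its probe sets ranged from 1.74 to 3.82. Pvt1, the RNA gene next to Myc, rose by 1.77 ± 0.24, and its 5 probe sets ranged from 0.47 to 1.77. The imprinted neighbours Peg10 and Sgce rose by 2.91 ± 0.42 and 1.13 ± 0.18. Ifi30 (-3.01 ± 0.25), Fn1 (-2.78 ± 0.36), Ctsh (-2.66 ± 0.39), Aif1 (-2.56 ± 0.20) and Mpeg1 (-2.19 ± 0.35) were lower. Apart from Bcl6 and Ifng, these genes were called in all 6 fits that left out an array.

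Small nucleolar RNA host genes, noncoding RNAs whose introns hold guides of ribosomal RNA modification, may fall together with the ribosomal protein genes. The falls of Snhg3 (-2.18 ± 0.28), Snhg4 (-2.12 ± 0.20), Dancr (-1.85 ± 0.29), Snhg12 (-1.65 ± 0.19) and Zfas1 (-1.63 ± 0.16) prompted the hypothesis. Among the 12 other host genes measured, whose values had not been looked at, 5 fell and 0 rose, with a median of -0.72 against a central 95% range of -0.17 to 0.22 in 10000 expression-matched lists. These were Gas5, Snhg1, Snhg6, Snhg7 and Snhg8. The other 7 did not pass, and of these Snhg16 (0.40 ± 0.18), Snhg18 (0.13 ± 0.20) and Snhg11 (0.06 ± 0.21) lay above 0. The test shows that the other host genes had a lower median than genes of like expression. It did not compare them with the ribosomal protein genes, and it does not show what lowered them. The matched lists draw genes independently, so their range may be too narrow if host genes vary together. All host genes were measured on the same arrays.

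Blocks of the genome that differ between strains could give neighbouring calls, since the mice had a mixed background. With families counted once, the largest number of called genes among 20 neighbouring tested genes was 6, against a 95th percentile of 7 in 10000 permutations (permutation p = 0.926). The tables give no sign of such blocks among the 18143 genes placed, 1084 of them called.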
